A study of Mus musculus with 464 samples.

How the data were processed

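The series holds single-cell RNA sequencing of mouse R1 embryonic stem cells, a line that was grown with 15% serum replacement and 1000 U/ml of the cytokine LIF before differentiation. Per the labels, the cells formed embryoid bodies in hanging drops for 48 hours and were then kept for 4 days in medium with retinoic acid, whose dose the labels state as 0.5 mM. Single cells were captured on a Fluidigm C1 instrument, cDNA was made with the SMART-Seq V4 chemistry, and libraries were made with Nextera XT. This chemistry copies full-length transcripts and adds no molecular identifiers, so reads cannot be reduced to molecules. Each of the 464 samples is labelled as 1 cell, and all carry the same label, so there is 1 group. The labels name no separate cultures, so the cells were treated as 1 sample. The chromatin data that the design text also mentions were not analysed here.

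The submitters' processing notes name STAR and RSEM, without versions, and the genome build mm10. The gene annotation and any filter on genes or cells are not given in the sources used here. The authors deposited a table with no stated unit, and its values were taken to be TPM (a measure of transcript share corrected for gene length), since RSEM gives that unit and the values are decimals whose sum in a cell never passes the total that TPM assigns to it. The sums ran from 54.2% to 95.1% of that total, so part of each cell's expression lies on genes that the table does not list. The table holds 21973 genes, of which 3751 were at 0 in every cell, and 69.7% of all values were 0. Its header line runs on into the row of the first gene, and the line was split there. TPM keeps no sequencing depth. Depth per cell is therefore unknown, and cells could not be thinned to a common depth. The number of genes with a value above 0 served as the only stand-in for depth.

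Column names fall into 2 sets by their names, with 228 and 236 cells, of which 224 and 234 were kept. The names end in a lane tag that differs between the sets, and what else the sets stand for is not stated. They were treated as a technical batch, and counts within each set are given beside many of the pooled ones. No 2 columns held identical values, but 55 columns of set 1 each had a near copy in set 2. Across genes detected in at least 10 cells, log2(TPM + 1) correlated at 0.95 to 0.99 within these pairs, with a median of 0.98, whereas the highest correlation of any other 2 columns was 0.92 and the median of the next best match of a paired column was 0.77. All 55 pairs had 1 column in each set and fell in the same cluster. They were noticed after the analysis was complete and were taken to be repeat measurements of the same cells, at a bound of 0.93. The 458 kept columns then hold 403 distinct cells. The analysis fixed beforehand keeps all columns, and shares, counts by cluster, co-detection and the tests of explanations were also computed with the set 2 column of each pair left out, called distinct cells in the text. Columns could not be tied to single samples of the labels, which has no effect here because all samples share 1 group. For gene positions, 21335 of the 21973 gene names matched the RefSeq annotation of assembly GRCm38.p6, the same build as mm10. The reference genome sequence at hand was of an older build and was not used.

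Cells were kept with at least 2000 genes above 0 and at most 20% of their total from mitochondrially encoded genes. This removed 6 cells and left 458. Of the removed cells, 2 had too few genes, 5 had too high a mitochondrial share, and 1 of these had both. A gene was called detected in a cell at 1 TPM or more. Doublets, meaning 2 cells in 1 capture site, were not called, because callers need counts. An alternative left out the 5% of cells with the most genes.

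Before the data were examined, 33 gene lists were fixed, 16 of cell type markers and 17 of gene groups, with 504 genes of which 498 are in the table. Xist, Tsix, H19, Meg3, Rian and Mirg were not analysed here. For clustering, log2(TPM + 1) was taken for genes detected in at least 10 cells, all listed genes were left out, and the 2000 genes with the highest variance over the trend with the mean entered a principal component analysis. A graph of the 15 nearest neighbours in 20 components was clustered with the Leiden method at resolution 1 and seed 0. Clusters were numbered by size. A listed gene was called higher or lower in a cluster by a rule of size: a mean TPM at least 2-fold above or below that of all other cells, detection in at least 10 cells, and 95% intervals of the detected shares that do not overlap. Each list's median log2 fold (with 0.01 TPM added to both means) was set against 10000 random lists of the same size matched on mean expression, as a description. Co-detection was counted as at least 3 detected markers of each of 2 lists.

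Cells of 1 sample are not replicates, so there are no p-values, no standard errors and no count of changed genes. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. They assume independent cells, so with 110 paired columns they are too narrow, and the values of the 2 column sets are not independent of each other. Genes were named by a rule fixed beforehand. From each list, up to 4 members detected in the largest share of cells and, per cluster, up to 4 members with the largest fold among those called higher could be named. Members detected in fewer than 10 cells were counted but not named, except for 15 genes fixed in advance. Some of the genes that the rule names are not reported here. The defining genes of a cluster were the 10 unlisted genes with the largest fold, among those detected in at least 25% of its cells and in at least 10 cells. Which clusters share a name was decided after the markers were seen: clusters with at least 13 of the 23 neural progenitor markers detected in at least 50% of their cells were called neural progenitor-like. This class holds 246 columns. That threshold was set after the data were seen, and clusters 6 and 9, with 11 such markers each, lie just below it. Cluster 7 was called neuron-like because 25 of the 32 neuron markers were higher in it, against at most 9 in any other cluster. Cluster 9, with 9, was first placed with it and was then left unnamed because cell cycle genes were higher in it. By the number of neuron markers detected in at least 50% of cells, clusters 1 and 9, with 24 each, are close to cluster 7, with 25. For the test of cluster 6 as a mixture, 460 endoderm and 258 neural genes were used that differ at least 10-fold between cluster 2 and this class and have a mean of at least 10 TPM in the higher one.

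The calling rule was tested on simulated data in which each gene was shuffled over cells and changes were planted in 60 cells, for the comparison of 1 cluster with all other cells over 13756 genes. It called 37 of 40 genes planted at 3-fold through more detecting cells, 39 of 40 at 5-fold, 2 of 40 at 1.5-fold, and 40 of 40 genes planted at 5-fold fewer cells. It called 0 of 40 genes that are detected in at least 90% of cells and were raised 3-fold, because their detected share cannot rise. It called 22 of 13556 unchanged genes. Shuffling evens out the number of genes per cell and breaks up the paired columns, whereas the clusters had medians of 4419 to 8080.5 genes. The share of unchanged genes called may therefore differ in the clusters. The clustering was tested in the same way and did not return the planted number of groups. Shuffled values with no groups at all gave between 8 and 10 clusters in 5 draws, so the number of clusters is no evidence for that many kinds of cells. With 3 planted groups and 200 genes per group, the setting run first gave 8 clusters, with 80.8% of cells in a cluster led by their own group where the largest planted group holds 60.7% of cells, and an adjusted Rand index of 0.16. Further settings, added after that outcome, gave 4 to 7 clusters, indices of 0.35 to 0.62 and 97.8% to 100% of cells in a cluster led by their own group, so planted groups were split more than mixed. When each gene was shuffled within the 6 classes used here, which come from the same data, exactly those 6 were returned. The first principal component held 15.3% of the variance in the deposited values and 0.56% to 0.57% in the shuffled ones.

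Alternatives fixed beforehand changed the detection threshold, the cell filter, the number of variable genes, components and neighbours, the resolution, the pseudocount, the seed, the clustering method (k-means, and nonnegative matrix factorization with 3 factors), the cell cycle signal, the held-out genes and the scaling of cells. Others were added after the data were seen: each column set alone, detection by rank within a cell, leaving out clusters 6 and 8, and 1 column of each near-identical pair. The computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.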

Results

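Gene expression was measured in single cells from mouse R1 embryonic stem cells after embryoid body formation and 4 days of retinoic acid, a vitamin A derivative that directs such cells toward neural fates. All cells belong to 1 group, and the design text names the clustering of cells as the aim, so the comparisons are between groups of cells within 1 culture condition. The cell filter removed 6 cells. A kept cell had a median of 6742.5 genes above 0 and a median mitochondrial share of 6.64%. The 2 column sets had medians of 6742.5 and 6733.5 genes, and sequencing depth is unknown. Near copies were found between the sets: 55 columns of set 1 each had a column in set 2 with a correlation of 0.95 to 0.99 across genes, and these pairs make up 24.02% of the kept columns. They were taken to be repeat measurements of the same cells. Shares and counts below are over all kept columns, called cells, as fixed beforehand, and values over distinct cells, with 1 column of each pair, are given beside many of them. There are no replicate cultures, so no p-value is given. Intervals cover counting error only and are too narrow to the extent that cells are repeated.

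Genes of the retinoic acid response were detected in most cells. Rarb, a retinoic acid receptor gene that is itself induced by retinoic acid, was detected in 91.05% of cells (95% interval 88.1 to 93.5) at a mean of 59.5 TPM. Crabp2, which encodes a carrier of retinoic acid, was detected in 96.9% of cells. Cyp26a1, which encodes an enzyme that degrades retinoic acid, was detected in 80.8% (76.9 to 84.3) at a mean of 349.1 TPM and a median of 74.6 TPM. Of the 19 genes in this list, 14 were detected in at least 10% of cells. Stra8, a retinoic acid target of germ cells, was detected in 15.5% (12.3 to 19.1). Over distinct cells, Rarb was detected in 90.3% (87.01 to 93.03) and Cyp26a1 in 78.4% (74.1 to 82.3), and the shares of the other genes in the plot of detected shares also stayed within their intervals.

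Anterior Hox genes, which pattern the hindbrain and neck region of the embryo, were broadly detected. Of the 15 genes of Hox paralog groups 1 to 5, 14 reached at least 10% of cells, led by Hoxa5 in 91.05% and Hoxb2 in 87.99%. Hoxb1 was detected in 19.4% (15.9 to 23.4). Of the 24 genes of paralog groups 6 to 13, 8 reached that share, led by Hoxb6 in 86.03% and Hoxb7 in 72.3%. Among regional brain genes, 1 of 10 in the forebrain and midbrain list (Pax2, 15.5%) and 3 of 8 in the hindbrain and floor plate list did so, among them Gbx2 in 26.2% and Egr2 in 14.4%.

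Of the 23 neural progenitor markers, 18 were detected in at least 10% of cells. Pax6, a transcription factor gene of neural progenitors on chromosome 2 (105668896 to 105698410, mm10), was detected in 81.7% (77.8 to 85.1) at a mean of 63.4 TPM, and Sox1 on chromosome 8 (12395519 to 12399555) in 33.2% (28.9 to 37.7). The Sox1 share depended on the threshold, with 46.5% for any value above 0, 17.03% for at least 5 TPM and 0.66% among the 4000 highest genes of a cell. Cdh2 was detected in 81.7% and Fabp7 in 80.1%. Of the 32 neuron markers, 29 reached that share. Tubb3, which encodes a neuronal tubulin, was detected in 75.3% (71.1 to 79.2).

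Pou5f1 and Nanog were rarely detected, while other members of the pluripotency list were found more widely. Pou5f1, which encodes Oct4 and is needed for the pluripotent state, was detected in 4 kept cells (0.873%, 0.238 to 2.22), and Nanog in 6 cells (1.31%, 0.482 to 2.83). Of the 23 members, 11 were detected in at least 10% of cells, among them Sall4 in 46.9%, Dppa5a in 34.7%, Klf4 in 32.5% and Klf5 in 27.1%. Of the 8 primed epiblast genes, 4 reached 10% of cells, led by the DNA methyltransferase gene Dnmt3a in 67.7%. Of the 7 markers of 2-cell-like cells, 0 did.

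A minority of cells carried endoderm markers. All 10 primitive endoderm markers were detected in at least 10% of cells. Gata4, on chromosome 14 (63198914 to 63271712), was detected in 26.4% (22.4 to 30.7), Sox17, on chromosome 1 (4490928 to 4497426), in 29.9% (25.8 to 34.3), and Foxa2, on chromosome 2 (148042877 to 148046969), in 27.9% (23.9 to 32.3). Of 12 parietal endoderm markers, 11 reached 10% of cells, as did 5 of 15 visceral endoderm markers and 6 of 10 epithelial and surface ectoderm markers. For other lineages the count was 2 of 12 for early mesoderm, 3 of 20 for mesenchyme, 3 of 9 for neural crest, 2 of 10 for trophoblast, 2 of 17 for endothelium and blood, 1 of 7 for cardiac muscle and 5 of 8 for germ cells. Twist1, a mesenchyme gene, was detected in 4.80% (3.03 to 7.18). Among the 4000 highest genes of a cell, Twist1 was found in 0.44%, Stra8 in 7.28% and Hoxb1 in 5.74%.

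Among the remaining gene groups, all 42 S phase and all 52 G2 and M phase genes were detected in at least 10% of cells, as were all 12 Notch pathway genes and all 9 housekeeping genes. The count was 10 of 12 for immediate early and heat shock genes, 9 of 10 for p53 targets, 17 of 18 for hypoxia and glycolysis, 4 of 10 for Wnt targets, 8 of 11 for BMP targets and 7 of 10 for FGF and ERK targets. It was 12 of the 13 imprinted genes in the table. Of 4 sex chromosome genes in the table, all Y-linked, 3 reached that share, led by Eif2s3y in 63.1%.

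**Figure D1:**
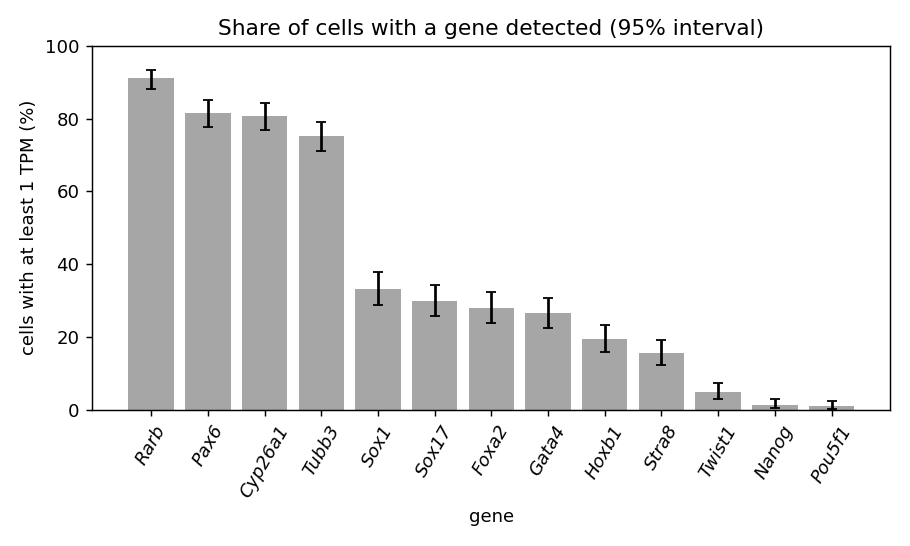
Share of the kept cells in which each of 13 genes fixed in advance was detected at 1 TPM or more, in percent; bars start at 0 and lines are exact 95% intervals for counting error. Rarb stood at 91.05% and Pou5f1 at 0.873%.

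Clustering without the listed genes gave 9 clusters of 20 to 68 cells. Because shuffled values also gave 8 to 10 clusters, the number itself carries no information, and clusters were read through the marker lists that had been held out. Clusters 1, 3, 4 and 5, with 53.7% of the kept cells (49.02 to 58.4), were neural progenitor-like: 13 to 15 of the 23 neural progenitor markers were detected in at least 50% of the cells of each. Cluster 7, with 52 cells (11.4%, 8.60 to 14.6), was neuron-like; together with cluster 9, which was left out of this class after the data were seen, it would hold 15.7% (12.5 to 19.4). Cluster 2, with 64 cells (13.97%, 10.9 to 17.5), was primitive endoderm-like. Clusters 6, 8 and 9 stayed unnamed, with 55, 21 and 20 cells. Clusters 6 and 9 each had 11 neural progenitor markers detected in at least 50% of their cells, just below the cut. Over distinct cells the neural progenitor-like share was 52.1% (47.1 to 57.1), the neuron-like share 12.4% (9.35 to 16.03) and the primitive endoderm-like share 13.9% (10.7 to 17.7). Within column sets 1 and 2, the neural progenitor-like share was 56.2% and 51.3%, the neuron-like share 10.7% and 11.97%, and the primitive endoderm-like share 14.3% and 13.7%. The share of cluster 6 was 9.38% (5.90 to 13.97) in set 1 and 14.5% (10.3 to 19.7) in set 2. Alternatives of the clustering gave a neural progenitor-like share of 51.97% to 66.1%, a neuron-like share of 9.83% to 19.7% and a primitive endoderm-like share of 12.8% to 22.5%. Cluster 6 was not found in 2 of 19 alternatives, cluster 8 was not found in 6 and cluster 9 not in 9, and cluster 9 held 1.99% when distinct cells were clustered anew. Clusters 8 and 9 had no match when either column set was clustered alone, and cluster 6 had none with set 1 alone. Counts within the sets, here and below, keep the clusters found in the pooled cells.

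**Figure D2:**
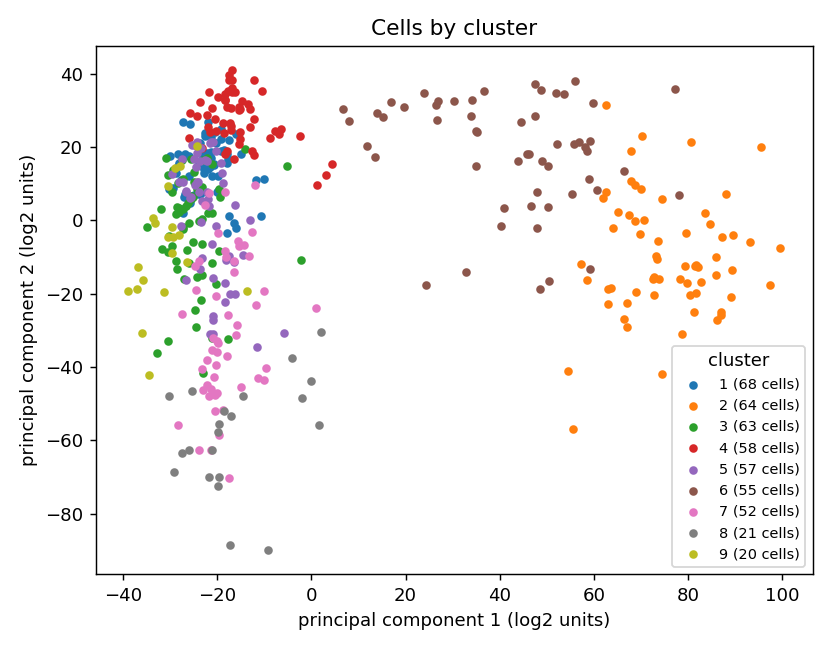
Each point is 1 kept cell on the first 2 principal components of log2(TPM + 1), coloured by cluster, with listed genes left out. The first component holds 15.3% of the variance.

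The primitive endoderm-like cells of cluster 2 had all 10 primitive endoderm markers, all 12 parietal endoderm markers and 11 of 15 visceral endoderm markers higher than in the other cells. Sox17 was 15.2-fold higher, at a mean of 185.7 against 12.2 TPM, and was detected in 96.9% (89.2 to 99.6) against 19.04% (15.3 to 23.3) of cells. Gata4 was 12.9-fold higher and Gata6 11.7-fold. Sparc and Col4a1, which encode proteins of the basement membrane, were 13.03-fold and 11.5-fold higher, though Sparc passed the rule in neither set alone. Ttr and Rbp4, which encode carriers of thyroid hormone and retinol, were 30.01-fold and 17.3-fold higher. Foxa2 was 9.81-fold higher. The median log2 fold of the primitive endoderm list was 3.37, above that of 100% of 10000 random lists. Within column sets 1 and 2, 9 and 9 primitive endoderm, 11 and 10 parietal endoderm and 8 and 8 visceral endoderm markers were higher. Of 10 epithelial markers, 7 were higher (7 and 6 within the sets), with the keratin genes Krt19 at 23.8-fold and Krt18 at 19.7-fold. The visceral endoderm count was 9 over distinct cells and 6 when differences of mean log2 values were used. It was 7 and 5 when column sets 1 and 2 were clustered alone, though with set 1 alone the group held more than the cells of cluster 2.

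The same cells had 12 of 23 pluripotency list members higher, among them Zfp42 at 14.3-fold and L1td1 at 13.5-fold, while Pou5f1 was detected in 1.56% (0.0396 to 8.40) of them and Nanog in 0 of 64, with an upper 95% limit of 5.60%. Within sets 1 and 2 the pluripotency count was 8 and 9, and over distinct cells 11. Neural genes were low: 19 of 23 neural progenitor markers, 28 of 32 neuron markers and 10 of 12 Notch pathway genes were lower. Within the sets these counts were 18 and 18, 25 and 25, and 10 and 8. The Notch pathway gene Hes1 went the other way and was called higher. Pax6 had a mean of 1.99 TPM against 73.4 TPM in the other cells. Of the 15 genes of Hox paralog groups 1 to 5, 13 were lower (13 and 12 within the sets), and 7 of 24 of groups 6 to 13 (7 and 7). The retinoic acid list was split, with 4 members higher and 6 lower (4 and 4 higher, 6 and 7 lower within the sets). Cyp26a1 was 8.84-fold higher, at a mean of 1473 against 166.6 TPM, and Rdh10, which encodes an enzyme that makes retinoic acid's precursor, was 12.6-fold higher, while Rarb was at 32.3 against 63.9 TPM with a fold of 0.51, just short of the rule. Over distinct cells its fold was 0.50 and it was called lower.

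Cluster 2 also had 20 of 42 S phase genes and 36 of 52 G2 and M phase genes lower, with 7 and 20 S phase genes and 19 and 30 G2 and M phase genes within column sets 1 and 2. Over distinct cells the counts were 15 and 27. The G2 and M phase count was 12 when column set 1 was clustered alone. No cluster matched cluster 6 there, and the primitive endoderm-like group held a larger share of the cells. That count is therefore not of cluster 2 alone. Of 12 immediate early genes, 6 were higher, with Atf3 at 9.06-fold (6 and 4 within the sets). Among imprinted genes 5 were higher, with Igf2, a fetal growth factor gene, at 4.84-fold, and 7 were lower. The higher count was 2 and 0 within the sets and 3 over distinct cells, and the lower count was 7 in each of these. Of 20 mesenchyme genes 3 were higher (2 and 1 within the sets), among them Twist1 at 13.9-fold, detected in 15.6% (7.76 to 26.9) of these cells. Igf2 and Twist1 passed the rule in set 1 but not in set 2. Of 11 BMP targets, 5 were lower and Bmp2 and Msx2 were higher, but Bmp2 was not called over distinct cells or within either set. Cells of this cluster had a median of 5982 genes, fewer than the 6934.5 of the neural progenitor-like cells. Rescaling each cell by its broadly detected genes shifted the log2 fold of a gene in this class by a median of 0.27. The genes outside the lists with the largest folds were Slc4a9, Cxcl10, Col6a1, Gkn2, Muc13, Procr, Apol7a, Plac8, Cyp2s1 and 8430408G22Rik, which helped to define the cluster. Muc13 and Cyp2s1 passed the calling rule in set 2 only.

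The neuron-like cells of cluster 7 had 25 of 32 neuron markers higher, with 24 and 22 within column sets 1 and 2. The median log2 fold of this list was 2.64, above that of 100% of the random lists. Nefl and Nefm, which encode neurofilament proteins, were 23.9-fold and 19.4-fold higher and were detected in all 52 cells. Mapt, which encodes the microtubule protein tau, was 17.9-fold higher and Stmn2 16.1-fold. Tubb3 was 6.14-fold higher, at a mean of 921 against 150 TPM. Cell cycle genes were low, with 32 of 42 S phase genes and 42 of 52 G2 and M phase genes lower. Within the sets these counts were 27 and 24, and 40 and 36. Of the Notch pathway genes, 5 of 12 were lower (4 and 3). Of the 15 genes of Hox paralog groups 1 to 5, 5 were higher, with Hoxb5 at 4.09-fold and Hoxb1 at 3.26-fold, as were 3 of 24 of groups 6 to 13. Within the sets the first count was 2 and 2 and the other 1 and 3. Hoxb5 passed the rule in set 1 only and Hoxb1 in neither. Pax5, a gene of the midbrain and hindbrain border and of some neurons, was 9.04-fold higher. Cyp26a1 was lower at 38.99 against 388.8 TPM, but the other cells include clusters 2 and 6, where it was called higher. Some calls rested on 1 column set. Aldh1a2 was 3.48-fold higher in the pooled cells but had folds of 0.11 in set 1 and 15.2 in set 2. En1 had folds of 1.014 and 16.2. Defining genes outside the lists were Prph, Nrsn2, Prima1, Mab21l1, Resp18, Sncg, Arhgap36, St8sia4, Vstm2l and Cartpt, of which Prima1 passed the calling rule in set 2 only.

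In the neural progenitor-like clusters 1, 3, 4 and 5, endoderm markers were low against all other cells. Those cells include clusters 2 and 6, where 10 and 9 of the 10 primitive endoderm markers were higher. Cluster 7 also had 9 of the 10 lower. In clusters 1, 3, 4 and 5, 8, 9, 7 and 8 of them were lower, with median log2 folds of the list of -5.62, -6.38, -3.73 and -5.85. Within column set 1 these counts were 3, 7, 5 and 4, and within set 2 they were 7, 7, 2 and 5. Cells of clusters 1, 3, 4 and 5 had medians of 7335.5, 5673, 8080.5 and 6525 genes. The calling rule uses detected shares, and whether gene number enters the calls in these clusters was not tested. In cluster 3, 9 of 42 S phase genes were higher, with Dtl at 2.72-fold and Mcm6 at 2.31-fold, 4 of 23 neural progenitor markers were higher, with Hes5 at 2.40-fold, and 22 of 32 neuron markers were lower. Within column sets 1 and 2 these counts were 2 and 9, 1 and 3, and 16 and 20, and over distinct cells 5 S phase genes were higher. In cluster 5, Hes5 was 2.48-fold and the proneural gene Neurog2 3.37-fold higher, and 3 of 12 Notch pathway genes were higher, with Notch3 at 2.84-fold and Notch1 at 2.15-fold. Within the sets 1 and 1 were higher, and 1 was lower in set 2. In cluster 1, Dbx1, a gene of interneuron progenitors, was 2.15-fold higher, but 1.78-fold and not called over distinct cells. Hoxb1, Egr2, Id1 and Msx1 were 2.56-fold, 2.98-fold, 2.36-fold and 2.29-fold higher, but Id1 and Msx1 were the 2 BMP targets called, with 0 and 2 called within the sets. In cluster 4, Rfx4 was 2.37-fold and the dorsal neural tube gene Pax3 2.02-fold higher. Zic1 was 2.72-fold higher in the pooled cells but 0.27-fold in column set 2. Of 13 imprinted genes 4 were higher, with Mest at 2.69-fold (3 and 2 within the sets, 2 over distinct cells). Of 20 mesenchyme markers 3 were higher, with Prrx2 at 5.75-fold (1 and 3 within the sets, 1 over distinct cells). Of the list members named here as higher, Dtl in cluster 3, Egr2 in cluster 1, and Rfx4 and Prrx2 in cluster 4 passed the rule in both sets. Neurog2 and Notch1 in cluster 5, Dbx1 in cluster 1 and Pax3 in cluster 4 passed it in neither, and the others in 1 set. Among the defining genes were Nacc2 and Fam174b in cluster 1, Lyst and Sfrp2 in cluster 3, Hpgds and Igfbp5 in cluster 4, and Prdm12 and Stc1 in cluster 5. Of these, Fam174b, Hpgds and Igfbp5 passed the calling rule in both sets, Nacc2, Sfrp2 and Prdm12 in 1, and Lyst and Stc1 in neither; Lyst did not pass it in the pooled cells.

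Cluster 6 held endoderm and neural markers in the same cells. Of its markers, 9 of 10 primitive endoderm, 11 of 12 parietal endoderm and 8 of 23 pluripotency list members were higher, with Sox7 at 5.90-fold and Nid1 at 4.53-fold (8 and 9, 10 and 11, and 10 and 7 within the sets). None of the neural progenitor markers was called higher, and the median log2 fold of that list was -0.69. Gata4 was detected in 92.7% (82.4 to 97.98) and Pax6 in 90.9% (80.05 to 96.98) of its 55 cells. The median over cells of the mean log2(TPM + 1) of neural progenitor markers was 1.95, between 2.78 in the neural progenitor-like cells and 0.14 in cluster 2. That of primitive endoderm markers was 4.58, against 0.69 and 5.26. Its cells had a median of 8000 genes, against 5982 in cluster 2 and 5673 to 8080.5 in the neural progenitor-like clusters. Stra8 was 15.3-fold higher and passed the rule in set 1 only. Of the cluster's Stra8, 92.4% came from 3 cells with at least 1000 TPM, a value chosen after the data were seen. Without these cells the Stra8 mean was 11.2 TPM, against 9.03 TPM in the other clusters. The other clusters include cluster 2, where Stra8 was also called higher. Cluster 9 had 9 of 32 neuron markers higher, with Insm1 at 10.4-fold and Neurod4 at 5.87-fold (4 and 5 within the sets), together with 16 of 52 G2 and M phase genes, with Top2a at 4.23-fold, and 9 of 42 S phase genes. In column set 1 alone 0 of these cell cycle genes passed the rule, and in set 2 alone 7 of each list did, with Top2a in neither. The genes Hes2 and Foxn4 led its defining genes, at 288.5-fold and 48.5-fold. Hes2 was detected in 7 of 20 cells and passed the rule in neither set alone, while Foxn4 passed in both. Cluster 8 had 5 of 32 neuron markers higher, with Nhlh1 at 5.02-fold (2 and 1 within the sets, Nhlh1 in set 1 only), and 30 of 42 S phase genes and 36 of 52 G2 and M phase genes lower, with 22 and 29 in column set 1 and 12 and 6 in column set 2, where it has 8 cells. Over distinct cells these counts were 24 and 28. Its cells had a median of 4419 genes. Their median mitochondrial share was 8.89%, against 8.62% in cluster 7 and 6.64% over all kept cells. Its defining genes, by falling fold, were Gm10722, Vmn2r49, Gm16513, Ankib1, Gm10800, Col11a1, Hyal1, Gm10801, Veph1 and Ccdc63. Ankib1, Col11a1 and Hyal1 did not pass the calling rule in the pooled cells. Gm10722, Gm10800 and Gm10801 stood at 170.8-fold, 111.8-fold and 92.9-fold. Of these 3, Gm10801 passed the rule in both sets and the others in neither. Gene models such as these resemble repeats, so their values are uncertain.

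**Figure D3:**
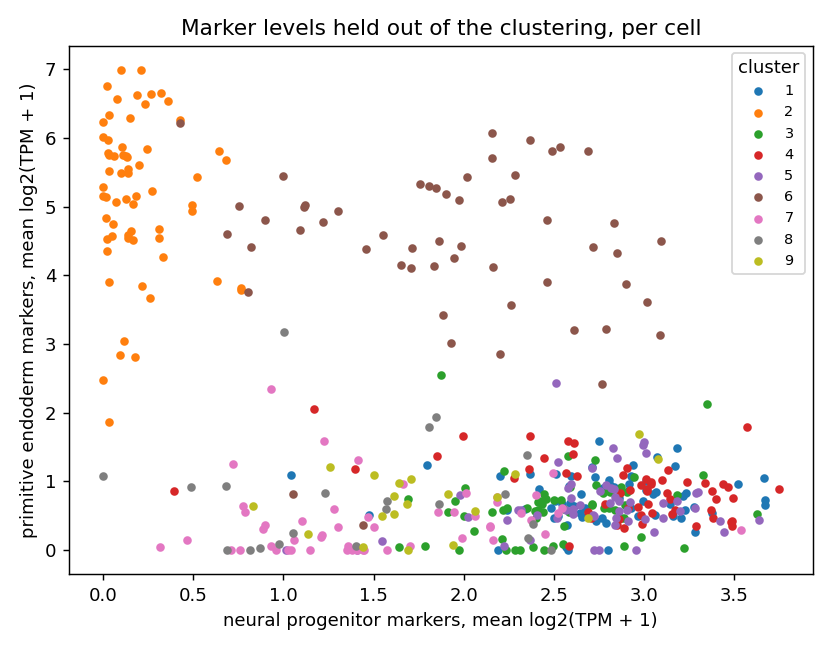
Each point is 1 cell, with the mean log2(TPM + 1) of 23 neural progenitor markers on the horizontal axis and of 10 primitive endoderm markers on the vertical axis, coloured by cluster. Cluster 2 lies at high endoderm and low neural values, and cluster 6 lies at high endoderm values and intermediate neural values.

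**Figure D4:**
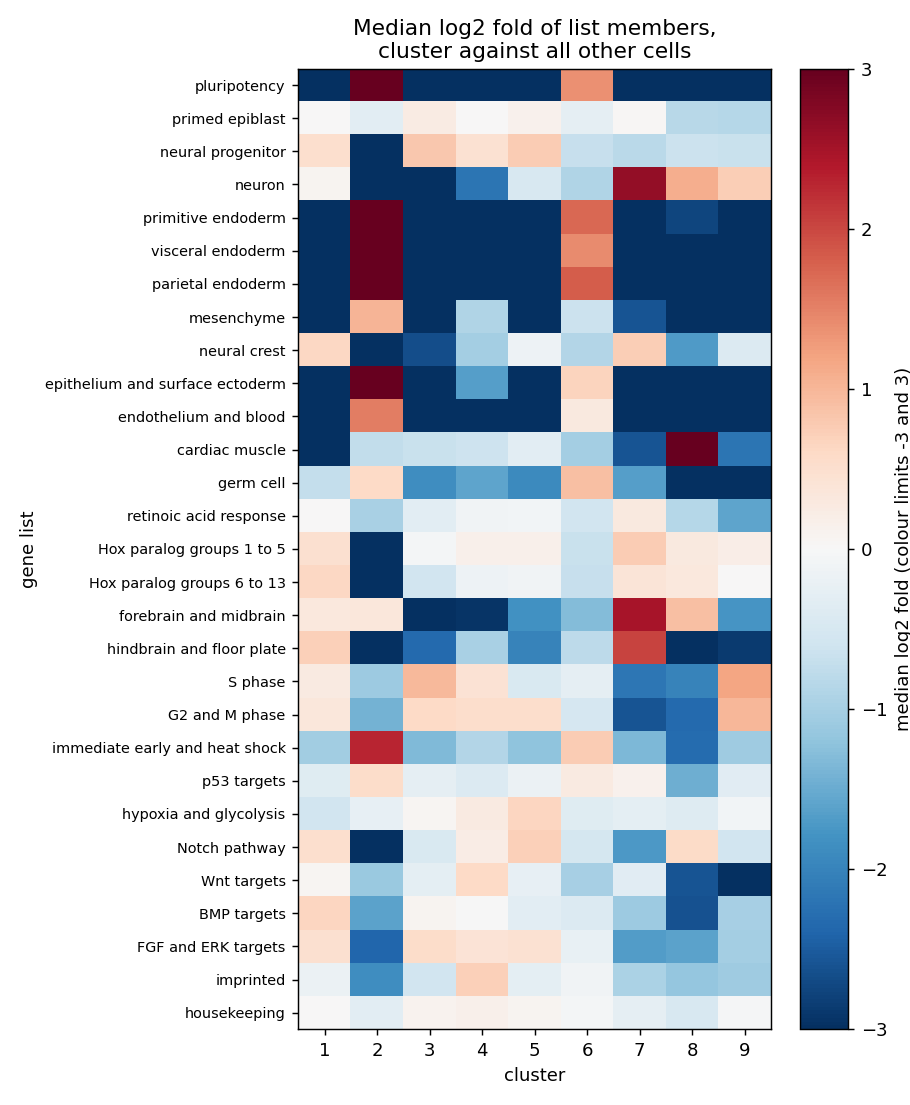
Median log2 fold of list members in each cluster against all other cells, for lists with at least 5 members detected in at least 10 cells; colours are limited to -3 and 3. The endoderm lists are high in clusters 2 and 6, and the neuron list is highest in cluster 7.

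Co-detection of markers of different lineages was counted in single cells. At least 3 neural progenitor and at least 3 primitive endoderm markers were detected together in 26.6% of cells (22.6 to 30.9), 0.80 times the number expected from the product of the shares. Of these cells, 53 were in cluster 6. The share was 21.4% in column set 1 and 31.6% in column set 2. Pluripotency and primitive endoderm markers were found together in 28.2% (24.1 to 32.5), 2.22 times the number expected, and 63 of these cells were in cluster 2. Pluripotency and neural progenitor markers were together in 22.3% (18.5 to 26.4), 0.76 times the number expected, and 55 of these cells were in cluster 6. Mesenchyme markers were found with neural progenitor markers in 26 cells (5.68%, 3.74 to 8.21), against 30.8 expected, and with primitive endoderm markers in 25 cells (5.46%, 3.56 to 7.95), against 13.3 expected. In each of these 2 pairs 12 cells were in cluster 6. Cells with both neural progenitor and primitive endoderm markers had a median of 7140 genes, against 6464.5 in the others. Over distinct cells 26.3% (22.1 to 30.9) had both. Without clusters 6 and 8, chosen after the data were seen, 16.5% of cells had both, and with detection among the 4000 highest genes of a cell 10.2% had both. In the same 2 alternatives pluripotency and neural progenitor markers were together in 10.99% and 5.08%, pluripotency and primitive endoderm markers in 18.8% and 18.3%, mesenchyme and neural progenitor markers in 3.66% and 0%, and mesenchyme and primitive endoderm markers in 3.40% and 0.442%.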

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

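Alternatives that use 1 column set, rank within a cell, 1 column of each near-identical pair, or leave out clusters 6 and 8 were chosen after the data were seen; the others were fixed beforehand. Alternative clusters were matched to the class that holds most of their cells. No paired analysis was possible because there is 1 group, and no replicate could be left out because there is 1 sample. Sequencing depth is unknown, so its effect was followed only through genes per cell. The cause of each shift below was not tested. Counts of members detected in at least 10% of cells kept within 1.5 times in 78 values, and 2 moved: with the 4000 highest genes of a cell, pluripotency went from 11 to 5 and mesenchyme from 3 to 0. Shares of cells with single genes left the interval in 39 values and stayed within it in all others; Sox1 ran from 0.66% to 46.5%. Counts of listed genes by cluster moved in 4 values and kept within 1.5 times in all others. Visceral endoderm members higher in the primitive endoderm-like cells went from 11 to 6 with differences of mean log2 values, 7 with column set 1 only and 5 with column set 2 only. G2 and M phase members lower in these cells went from 36 to 12 with column set 1 only. With column set 1 only, no cluster matched cluster 6 and the primitive endoderm-like group held a larger share. Neither of its counts is therefore of cluster 2 alone. For the rescaled values, 2 cells of cluster 8 had no scaling factor and were left out. Rescaling shifted the log2 fold of a gene by a median of 0.27 in the primitive endoderm-like cells. This median shift was 0.47 in cluster 8 and -0.23 in the neural progenitor-like cells, over genes detected in at least 10 cells.

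Shares of cells in clusters stayed within the interval, or counts of clusters within 1.5 times, in all but 14 values. The neural progenitor-like share of 53.7% became 62.9% with 30 neighbours, 62.7% with 1000 variable genes, 58.5% with 4000 variable genes and 66.1% with column set 1 only. Nonnegative matrix factorization gave 3 groups in place of 9, with 19.2% neuron-like and 22.5% primitive endoderm-like. Column set 1 alone gave 5 clusters and 22.3% primitive endoderm-like, and column set 2 alone gave 19.7% neuron-like. Cluster 9 became 7.21% with k-means, 7.64% with the cell cycle regressed out and 1.99% with 1 column of each near-identical pair. Cluster 6 became 8.51% without the 5% of cells with the most genes. There was no cluster matching cluster 6 in 2, cluster 8 in 6 and cluster 9 in 9 of 19 alternatives, which then have no value. Clusters 8 and 9 had no match with either column set alone, and cluster 6 had none with column set 1 alone. The adjusted Rand index against the clusters used ran from 0.24 to 0.96.

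Co-detection depended most on the settings, with 27 values within the interval and 23 outside. In the order pluripotency with neural progenitor, pluripotency with primitive endoderm, neural progenitor with primitive endoderm, neural progenitor with mesenchyme, and primitive endoderm with mesenchyme, at least 2 markers of each list gave 43.4%, 40.6%, 51.97%, 19.4% and 17.2%. The 4000 highest genes of a cell gave 5.08%, 18.3%, 10.2%, 0% and 0.442%. Leaving out clusters 6 and 8 gave 10.99%, 18.8%, 16.5%, 3.66% and 3.40%. Any value above 0 gave 33.4% for the first and 38.9% for the third pair. A value of at least 5 gave 14.2% for the first, 17.2% for the third, 1.75% for the fourth and 2.18% for the last pair. Column sets 1 and 2 gave 21.4% and 31.6% for the third pair.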

Other observations

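The tests in this part were chosen after the result was seen, except the test of Gm10800 within clusters; mean Gm10800 values per cluster had been seen before that test too. Transmitter genes in the neuron-like cells of cluster 7 were looked up after their values were seen. Sst, which encodes the peptide somatostatin, had a mean of 1600 TPM against 54.9 TPM in the other cells, with a median of 75.8 TPM and detection in 67.3% (52.9 to 79.7) of the 52 cells. Gad2, which encodes an enzyme of GABA synthesis, was detected in 57.7%, Th, of catecholamine synthesis, in 44.2%, and Chat and Slc18a3, of acetylcholine synthesis and storage, in 21.2% and 34.6%. Chat and Slc18a3 were detected together in 10 cells, against 3.81 expected from the product of their shares, and Chat and Gad2 in 5 cells, against 6.35 expected. Th and Chat were detected together in 9 cells, against 4.87 expected, and Sst and Gad2 in 24, against 20.2. Over distinct cells these 4 counts were 10, 5, 9 and 23 of 50 cells. The vesicular glutamate transporter gene Slc17a6 was detected in 9.62%. Of the other acetylcholine and catecholamine genes looked up, Slc5a7 was detected in 7.69% and Dbh in 0 of the 52 cells. Of the 3 cells with at least 1000 TPM of Stra8, all in cluster 6, the values were 2950, 2342 and 1737 TPM.

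Cluster 6 holds endoderm and neural genes together. A state of its own would bring genes of its own. These were counted at a mean of at least 5 TPM and detection in at least 25% of its cells. Only 3 genes (C2cd4b, Fkbp14 and Tnfaip2) were also at least 3-fold above both cluster 2 and the neural progenitor-like cells. The low count speaks against a state with many strong genes of its own. It does not speak against cells on a path between cluster 2 and the neural progenitor-like cells. Over genes that differ at least 10-fold between those cells, its median weights were 0.43 and 0.50, and their sum of 0.93 is consistent with 2 cells captured together; cells on such a path could give the same sum, so the hypothesis of doublets is open. Over distinct cells the sum was 0.95 and 2 such genes were left. The defining genes of cluster 6 were led by Zar1, at 9.26 TPM against 0.65 TPM in all other cells. Fgf2 followed, at 2.23 against 0.16 TPM. Neither passed the cuts for genes of its own. Zar1 was not at least 3-fold above both other kinds of cells. Fgf2 lay under the cut of 5 TPM, as did the defining genes C2cd4a, Enpep, Pde8a, Afmid and Trpc5os. Genes of low level, or with a smaller excess, were therefore not counted, and the low count does not speak on them. Free RNA between wells could not be excluded by the value set for it, since the neural progenitor-like cells had a median endoderm weight of 2.41%, between the bounds of 2% and 10%, while the lowest cell of cluster 6 had 11.1%. No biological explanation named by the design was tested, as there is 1 group.

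Satellite-like gene models such as Gm10800 are among the 10 defining genes of cluster 8, beside genes of other kinds such as Ankib1 and Col11a1. Whether libraries of low yield are the cause of the high Gm10800 values is left open. Cells with few genes had more Gm10800 in 1 of the 8 other clusters. But Gm10800 was among the genes that formed the clusters, which may have drawn cells rich in it into cluster 8. The count of clusters therefore decides nothing. Within cluster 8 the cells with the fewest genes had a median of 2052 TPM against 582 TPM in those with the most, and over distinct cells 2450 TPM against 257.6 TPM, with 5 cells each. Over all kept cells, the 25% with the fewest genes had a median of 7.53 TPM against 10.03 TPM in the 25% with the most, yet 30 against 7 of them had at least 100 TPM, a value chosen after the data were seen. Of the 25 neuron markers higher in cluster 7, 48.0% had at least 50% of that mean in cluster 8, between the bounds set, so whether these may be neurons could not be told.

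Pluripotency list genes were higher in the primitive endoderm-like cells. Residual pluripotent cells would bring Pou5f1 or Nanog, and 1 of the 58 cells with Dppa5a detected either (1.72%, 0.0436 to 9.24), which speaks against them as the source. In cluster 6 the median endoderm weight of these 12 genes was 0.62 against 0.43 for other endoderm genes, a distance of 0.18 under the bound of 0.2. Over distinct cells the distance was 0.21, past the bound, so this test does not tell whether the genes belong to the endoderm-like cells themselves. It rests on cluster 6, whose make-up is open, and does not measure cluster 2. In cluster 2 itself, Dppa5a was detected in 58 of 64 cells. At least 3 pluripotency list members and at least 3 primitive endoderm markers were detected together in 63 of the 64. Members of the list were therefore found in nearly every endoderm-like cell, which argues against a small subset of cells as their source.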
